A study of Mus musculus with 12 samples.

How the data were processed

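RNA from sorted mouse GMP was labelled with Cy3 by the Low Input Quick Amp kit and hybridised to 12 Agilent one-colour arrays on 4 slides, per the labels' protocols. Groups and replicate numbers were taken from the sample labels: wt (n = 4), ko (n = 4), ERt2 (n = 2) and RUNX1-ERt2 (n = 2). The wt and ko replicates 1 and 2 lay on slide 1 and replicates 3 and 4 on slide 2, which was scanned under another protocol name; ERt2 and RUNX1-ERt2 lay on slide 3 and slide 4. The spot intensities were deposited as scanner output that Agilent Feature Extraction had background-subtracted and detrended, per the file headers, with no normalization between arrays. The version in the file headers is not the version 9.1 in the submitters' processing notes. The authors' series matrix holds the same processed signal divided by the median of the array, as found by setting each column against the scanner values, with column medians of 0.91 to 0.94. Its 4 transplant columns matched their own arrays, and its 8 wt and ko columns each matched another replicate of the same group, 1 with 3 and 2 with 4. The scanner files were used for all values other than those of this alternative.

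Control spots and spots marked non-uniform or as population outliers by the scanner software (129 to 207 per array) were left out, spots of one probe were averaged, and log2 processed intensity was taken minus the 75th percentile of each array. Of 39429 probes, 27234 were named through their accession in a RefSeq table (GRCm38.p6, used for names only), 3576 through a current symbol and 565 through a synonym, and 8054 kept the name in the file; 28409 had a gene symbol and 11020 a clone name or none. Coordinates are those of the files (mm9). A probe was tested if it was well above background on every array of at least 1 group, and each symbol was represented by its probe with the highest mean over all arrays, which left 17907 genes, 13228 of them named. Where other probes of a named gene moved otherwise, the text says so.

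Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of group means and a slide term over the 12 arrays, so that all groups share one estimate of the spread; 7 residual degrees of freedom were joined by 2.11 prior ones. The slide term is fitted to the wt and ko arrays only, and it alters the p-values of the other comparisons through the shared estimate of the spread. P-values were adjusted by Benjamini and Hochberg over all genes with a threshold of 0.05. For a gene not well above background on any array of 1 group, the fold is a lower bound: the mean of the bright group over the mean, in the dim group, of the higher of the lowest signal among probes well above background on the array and the probe's own signal. Gene lists (28, of which 27 had at least 5 tested members) were tested with camera, two-sided, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Counts of members past the threshold are given over all genes and adjusted over the list alone. The lists are Runx family and partners; stem and early progenitor; megakaryocyte and platelet; erythroid; adhesion and niche receptor; primary granule and promyelocyte; late neutrophil; monocyte and macrophage; dendritic cell and MHC class II; eosinophil, basophil and mast cell; B lineage; T and NK cell; stroma and endothelium; cell cycle; cell cycle brakes and D cyclins; ribosome biogenesis; interferon response; Toll-like receptor and NF-kB; immediate early and heat shock; p53 target; unfolded protein response; hematopoietic transcription factor; Hox and Meis; cytokine receptor; glycolysis and hypoxia; cholesterol synthesis; RUNX1 targets in other work; and sex-linked genes. Several genes belong to more than 1 list.

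The genes named were chosen by a rule: for the first and second comparison the 10 largest rises and 10 largest falls among named genes past the threshold whose arrays separate the groups, up to 4 members of each list with the largest change past the threshold or else the member with the smallest p, Runx1, Runx2, Runx3 and Cbfb, and the 10 genes changed most in opposite directions; for the third comparison the 5 largest rises and falls and 1 member of each list. The groups, tests, lists, this rule and the first set of other settings were fixed before the data were examined. A few further members and the gene families of the closing section were named after their values were seen. A few genes chosen by this rule are not reported here; counts of genes and list members include them, and the scan for single arrays that stand apart leaves them out.

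The first set of other settings was normexp background correction (offset 50) on mean and background intensity, quantile normalization, the array median in place of the percentile, the series matrix, no filter on dim probes, probes well above background on all 12 arrays, no slide term, the replicate number as a block, only the arrays of the groups compared, a trended and robust prior, at least a 2-fold change, the mean of all probes of a gene, leaving out each array in turn, and each slide alone. Added after seeing the data were an adjustment for probe GC content (a lowess curve of span 0.2 per array), genes with probes of at least 34% GC, a crossed pairing of the transplanted arrays, and counts of list calls with the estimated correlation. Where leaving out an array left 1 in its group, that array is assumed to vary like the other groups.

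The replicate numbers come from the labels. Deviations of wt and ko arrays of the same number from their group means correlated across genes at 0.373, 0.354, 0.176 and 0.674, all above 0.1. Arrays of the same number share a slide, and on slide 1 those of different numbers correlated at 0.317 and 0.451. The values therefore do not show that the numbers pair the samples. For ERt2 and RUNX1-ERt2 the same-number value was −0.19. The blocked value is given as another setting where it changes the call of a gene or list named in the report. The numbers also contain the slide: with deviations taken within slides, the same-number correlations were −0.027 on slide 1 and 0.431 on slide 2. In the third comparison the replicate block and the crossed pairing set the replicate 1 levels of the groups against each other, not the group means. Their values there answer another question than the main fit.

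The fit was tested on simulated arrays of the same 17907 genes in which 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. These had independent normal noise of each gene's residual spread, no slide effect and no correlation between genes. The shares below hold for such data and may differ for the real arrays. For ko against wt, 38.8%, 65.7% and 92.4% of these were called with the right sign, for RUNX1-ERt2 against ERt2 5.97%, 46.3% and 84.8%, and for ERt2 against ko 19.4%, 59.7% and 89.4%; of 17707 unchanged genes 5, 4 and 8 were called. All 35 divisions of the 8 wt and ko arrays into groups of 4 were refitted. Other tools were the R package data.table (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.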

Results

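Gene expression was measured in mouse granulocyte-monocyte progenitors (GMP), the bone marrow cells from which neutrophils and monocytes arise, on 12 one-colour Cy3 arrays. Wild-type GMP (wt, 4 arrays) came from mice with intact Runx1 alleles and the vav-Cre transgene, which drives Cre recombinase in blood cells. Runx1-deleted GMP (ko, 4 arrays) came from mice with floxed Runx1 alleles and the same transgene. Runx1 encodes a DNA-binding transcription factor of blood cell development. In the remaining groups, bone marrow of Runx1-deleted donors, taken 3 days after 150 mg/kg of the cytostatic drug 5-fluorouracil, received a retrovirus that carried GFP with either RUNX1-ERt2, a RUNX1 protein fused to a tamoxifen-responsive hormone-binding domain, or ERt2, that domain alone. The cells were transplanted into lethally irradiated mice, tamoxifen (49.5 µg/g) was given on 3 days 6 weeks later, and viable GFP-positive GMP were sorted after a further 24 h (ERt2 and RUNX1-ERt2, 2 arrays each). The protocol speaks of tamoxifen for only a part of the mice, whereas the labels of all 4 transplanted samples name it, and the labels are followed here.

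Between 53.5% and 63.2% of the 39429 probes were well above background on an array. The median processed signal of an array lay between 65.4 and 98.6 in wt and ko GMP and between 43.1 and 59.7 in the transplanted groups, so the latter arrays were dimmer. No spot was saturated. The wt and ko arrays were spread evenly over slide 1 and slide 2, whereas each transplanted group lay on a slide of its own. The number of arrays limits the precision, and as the labels do not say that the arrays of a group came from separate animals, the p-values measure the spread between these samples, which may be partly technical. Differences are on the log2 scale with their SE from the limma fit, and all 17907 genes with signal in at least 1 group were tested.

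The Runx1 signal was higher in Runx1-deleted than in wild-type GMP. The brighter of 2 Runx1 probes (chromosome 16, 92605785 to 92605844, mm9) lay at 1.71 ± 0.54 (SD, n = 4) in wt and 3.40 ± 0.58 (SD, n = 4) in ko, in log2 units relative to the 75th percentile of each array. The difference was 1.69 ± 0.17 (limma adjusted p = 0.00025), with 1.74 on slide 1 and 1.63 on slide 2, and the other probe (92604413 to 92604472) gave 1.61 ± 0.11. Where these probes lie relative to the floxed segment is not given in the sources used here, so they do not check the deletion. In the transplanted groups the brighter probe measured 3.22 ± 0.11 (SD, n = 2) with ERt2 and 2.13 ± 0.29 (SD, n = 2) with RUNX1-ERt2, a difference of −1.09 ± 0.24 (adjusted p = 0.012) that no longer passed without ERt2 replicate 1 (adjusted p = 0.0701), without RUNX1-ERt2 replicate 2 (0.0864) or without the slide term (0.156). The other probe differed by −0.94 ± 0.15. Runx1 did not differ detectably between ERt2 and ko GMP (−0.18 ± 0.21, adjusted p = 0.47).

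Runx3 and Runx2 moved the same way. Runx3 was higher in ko than in wt by 0.49 ± 0.10 (adjusted p = 0.0098; 0.48 and 0.50 on the slides) and lower with RUNX1-ERt2 than with ERt2, at −1.89 ± 0.15 (adjusted p = 4.4e-05). Runx2 rose by 0.53 ± 0.14 in ko (adjusted p = 0.022; 0.69 and 0.37), a call that ended without any 1 of 5 arrays (highest adjusted p = 0.0716, without wt replicate 2) and with normexp background correction (0.445), and fell with RUNX1-ERt2 (−1.32 ± 0.19, adjusted p = 0.0016). Cbfb, the shared binding partner of RUNX proteins, did not pass in either comparison (−0.24 ± 0.12, adjusted p = 0.17, and −0.23 ± 0.17, adjusted p = 0.39). Of the 6 measured members of the list of Runx family and partners, 4 rose in ko and none fell, over all genes and adjusted over the list alone (median 0.51; 0.56 and 0.43 on the slides; camera adjusted p = 0.0133, adjusted p = 0.492 with an estimated correlation). With RUNX1-ERt2, 3 members fell by either adjustment, and the list as a whole did not pass (adjusted p = 0.0578).

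The first comparison asked which genes differ when Runx1 is deleted in GMP. The largest rise of a named gene measured in both groups was that of Jam3, an adhesion molecule of cell junctions, at 6.32 ± 0.38 (limma adjusted p = 1.9e-05; 6.09 on slide 1 and 6.56 on slide 2). It was followed by Dlk1, an imprinted gene for a Notch-related surface protein (5.50 ± 0.24; 5.68 and 5.31), by Zfp711 and Fhdc1 (5.45 ± 0.32, Zfp711 being well above background on 2 of 4 wt arrays, and 5.38 ± 0.38) and by the CD200 receptor gene Cd200r4 (4.86 ± 0.29). Prss34, a basophil protease with the deepest fitted change, fell by 8.10 (SE 0.56, adjusted p = 3.6e-05; −8.26 and −7.93; well above background on 2 of 4 ko arrays), and Fcer1a, the alpha chain of the IgE receptor, was at least 54.4-fold lower. Il17rb (−6.11 ± 0.56), Afap1 (−5.81 ± 0.31), Scin, which encodes an actin-severing protein (−5.70 ± 0.42), and the protease gene Gzmb (−5.26 ± 0.53) fell as well. Il17rb was well above background on 1 of 4 ko arrays and Afap1 on 3, so the size of these falls is less certain. All arrays of one group lay above all arrays of the other for each of these genes.

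In all, 2065 genes were higher and 2472 lower in ko, of which 655 and 627 changed at least 2-fold. Without 1 array the lower count ranged from 1444 to 2585. The lower count was 1397 with the array median and 1328 with the series matrix, where 1876 and 1884 genes were higher, so which direction is the larger depends on the scaling. Of all 17907 genes 74.4% had the same sign on both slides. Across genes, which are not independent replicates, the differences on slide 1 and slide 2 had a Pearson correlation of 0.71 and a Spearman correlation of 0.64. Among genes that were not well above background on any array of one group, a fold is given as a lower bound, the bright group's mean against the lowest level the arrays of the dim group could measure. In ko, Pcnx2 was at least 28.5-fold higher, C1qtnf7 at least 23.8-fold, Itgb6, an integrin, at least 12.3-fold and Nrg3 at least 6.22-fold, while Bdh2 was at least 13.6-fold lower, Ephx2 at least 11.7-fold and the adhesion gene Cdh1 at least 11.4-fold. Tceal3 was at least 21-fold lower. Of these, the calls of Nrg3 and Itgb6 ended with normexp background correction.

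**Figure D1:**
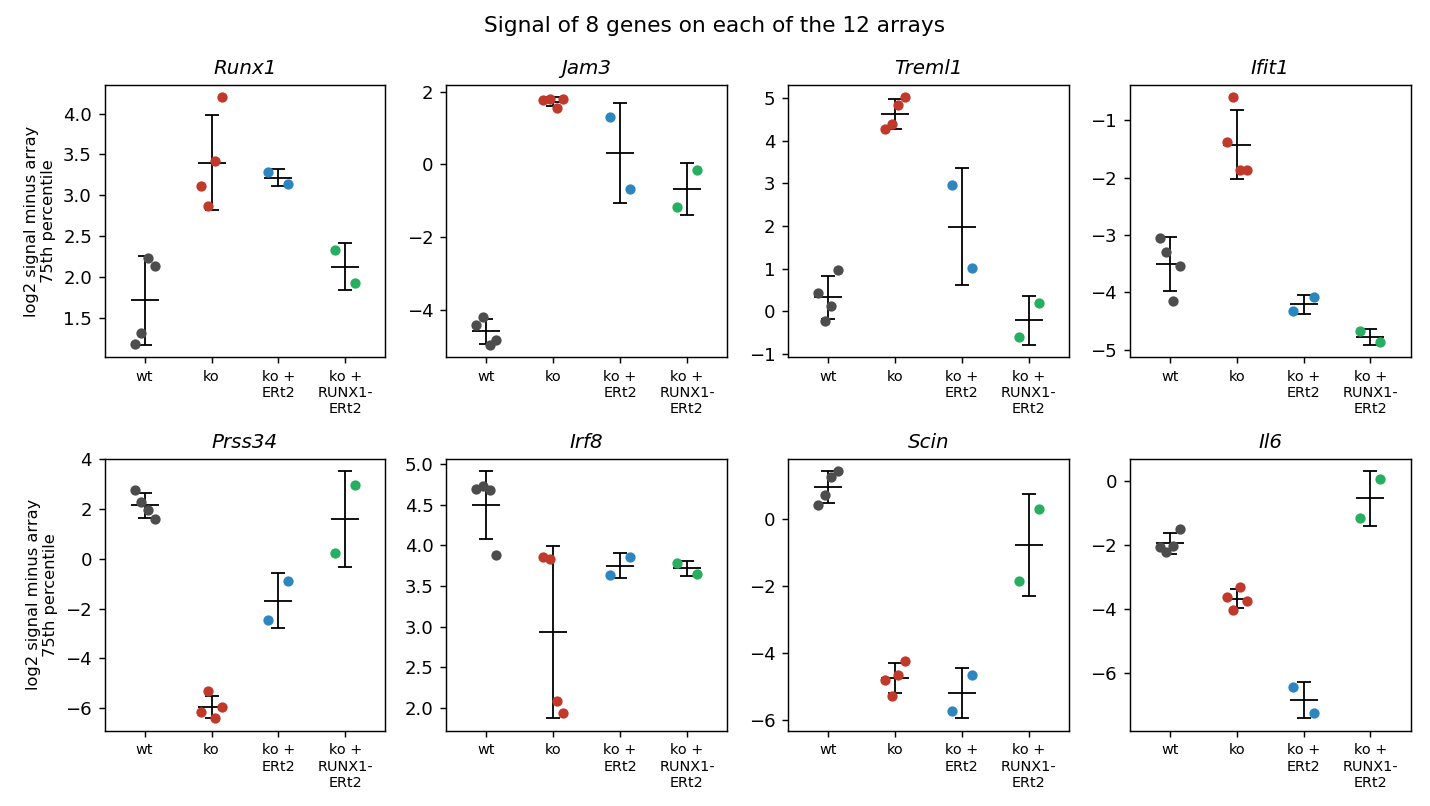
Signal of 8 genes on each array, in log2 units relative to the 75th percentile of the array; points are single arrays and bars the mean ± SD of each group (4 wt, 4 ko, 2 ERt2 and 2 RUNX1-ERt2). Jam3, Treml1, Ifit1 and Runx1 were higher in ko than in wt, Prss34, Scin, Irf8 and Il6 lower.

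Megakaryocyte and platelet genes rose in Runx1-deleted GMP. Of 33 measured members, 16 were higher and none lower over all genes, and 19 and none adjusted over the list alone; the median was 1.19, with 1.33 on slide 1 and 1.30 on slide 2 (camera adjusted p = 1.7e-09, adjusted p = 0.492 with an estimated correlation). Clec1b, a platelet activation receptor, rose by 4.41 ± 0.65 (3.59 and 5.22; well above background on 3 of 4 wt arrays), Treml1, a receptor of platelet granules, by 4.30 ± 0.40 (4.22 and 4.38), the von Willebrand factor receptor subunit Gp5 by 2.81 ± 0.34 and the thrombin receptor F2r by 2.65 ± 0.25. Hematopoietic stem and early progenitor genes rose more often than they fell, with 10 of 28 higher and 4 lower by either adjustment. The median was 0.49, with 0.53 on slide 1 and 0.26 on slide 2 (camera adjusted p = 0.0015, adjusted p = 0.588 with an estimated correlation). Among them were Tek, the angiopoietin receptor (3.00 ± 0.20), Slamf1 (2.96 ± 0.36) and Esam (2.93 ± 0.41). Adhesion and niche receptor genes, which include Jam3 and share genes such as Tek and Esam with the stem cell list, had 14 of 37 members higher and 4 lower (18 and 4 adjusted over the list alone), with the integrin gene Itga9 at 3.89 ± 0.20. The median was 0.34, with 0.47 on slide 1 and 0.18 on slide 2 (camera adjusted p = 7.6e-05, adjusted p = 0.492 with an estimated correlation).

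Erythroid genes moved in opposite directions on the 2 slides. Of 26, 6 were higher and 2 lower by either adjustment (adjusted p = 0.358), and the median was −0.01, with −1.25 on slide 1 and 0.89 on slide 2. Alas2, the first enzyme of heme synthesis in red cells, rose by 2.16 ± 0.40 and the globin gene Hbb-b2 by 2.13 ± 0.36, while Car1, a carbonic anhydrase, fell (−3.11 ± 0.77, adjusted p = 0.019; −5.14 and −1.08; adjusted p = 0.0517 with the replicate number as a block, and 0.0602 without wt replicate 2, the highest of 4 such values). Of 36 hematopoietic transcription factor genes, 10 were higher and 5 lower (10 and 6 adjusted over the list alone), led by Gata3 (2.36 ± 0.21), Irf8 (−1.57 ± 0.28), Id1 (1.46 ± 0.31) and Meis1 (1.34 ± 0.20). The median was −0.02, with −0.01 on slide 1 and 0.02 on slide 2 (camera adjusted p = 0.392). Of 17 Hox and Meis genes, 5 were higher and 2 lower by either adjustment. The median was −0.11, with −0.13 on slide 1 and 0.01 on slide 2 (camera adjusted p = 0.392). Pbx3, a partner of Hox proteins, rose by 1.62 ± 0.21.

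Genes of the monocyte and dendritic cell fates were lower in Runx1-deleted GMP. Of 23 monocyte and macrophage genes, 9 fell and none rose by either adjustment. The median was −0.55, with −0.47 on slide 1 and −0.51 on slide 2 (camera adjusted p = 0.0179, adjusted p = 0.647 with an estimated correlation). The fractalkine receptor Cx3cr1 fell by 3.01 (SE 0.37; −2.05 and −3.96), Irf8, a transcription factor required for monocyte and dendritic cell development, by 1.57 (SE 0.28; −0.87 and −2.26), and the chemokine receptor Ccr2 by 1.34 (SE 0.24; −1.20 and −1.47). The call of this list ended without wt replicate 3 (adjusted p = 0.0916), without ko replicate 4 (0.0925), without the slide term (0.0514) and on slide 1 alone (0.114). Of 15 dendritic cell and MHC class II genes, 6 fell and none rose (7 and none adjusted over the list alone), among them the invariant chain gene Cd74 (−1.74 ± 0.38) and the integrin gene Itgax (−1.35 ± 0.30). Without the slide term these did not pass (adjusted p = 0.0959 and 0.0664). The median was −0.41, with −0.69 on slide 1 and −0.59 on slide 2 (camera adjusted p = 0.00575, adjusted p = 0.497 with an estimated correlation). H2-Aa (−1.52 ± 0.47, adjusted p = 0.042; 0.0512 with the replicate number as a block) and H2-Eb1 (−1.68 ± 0.44) lost their calls without single arrays (highest adjusted p = 0.106, without wt replicate 2, and 0.0611, without ko replicate 2).

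Primary granule and promyelocyte genes fell in 4 of 14 cases and rose in none (7 and none adjusted over the list alone), with a median of −0.47 (−0.21 and −0.72). The list did not pass (adjusted p = 0.0513, adjusted p = 0.647 with an estimated correlation) but did with the replicate number as a block (adjusted p = 0.0428) and in 13 further settings. The serine protease gene Prss57 fell by 2.11 (SE 0.39; −2.12 and −2.10) and Ms4a3 by 1.56 (SE 0.34; −1.41 and −1.71). Cathepsin G (Ctsg, −0.74 ± 0.23) and myeloperoxidase (Mpo, −0.44 ± 0.14) passed narrowly, both at adjusted p = 0.045, and neither passed with the replicate block (0.0640 and 0.0711) or without wt replicate 3 (0.114 and 0.106). Late neutrophil genes showed no common shift (1 of 28 higher and 3 lower, 1 and 2 adjusted over the list alone). The median was −0.08, with −0.86 on slide 1 and 0.53 on slide 2 (camera adjusted p = 0.71). The chemokine receptor gene Cxcr2 rose by 1.33 ± 0.28 and Padi4, the enzyme of histone citrullination, fell by 1.06 (SE 0.18).

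Eosinophil, basophil and mast cell genes moved in both directions (4 of 18 higher and 5 lower, 4 and 6 adjusted over the list alone). The median was −0.37, with −0.59 on slide 1 and −0.18 on slide 2 (camera adjusted p = 0.402). Beside Prss34 and Fcer1a, the basophil protease gene Mcpt8 fell by 3.34 (SE 0.12; −3.15 and −3.54), whereas Cd200r3 rose by 4.16 ± 0.15 (4.49 and 3.83). Lymphoid lists did not pass with the main fit. None of 15 B lineage genes rose and 3 fell (none and 2 adjusted over the list alone), with Ms4a1, which encodes CD20, at least 2.74-fold lower. The median was −0.50, with −0.73 on slide 1 and −0.31 on slide 2 (camera adjusted p = 0.154). This list passed without ko replicate 3 (median −0.99, adjusted p = 0.0124) and with normexp (0.0498). Of 23 T and NK cell genes, 1 was higher and 2 lower by either adjustment: Gata3 rose, Nkg7 fell by 1.38 (SE 0.19) and the kinase gene Lck by 1.30 (SE 0.25). The median was 0.14, with −0.29 on slide 1 and 0.51 on slide 2 (camera adjusted p = 0.536, and 0.0367 on slide 2 alone). Of 9 stroma and endothelium genes, 1 was higher and 1 lower (2 and 2 adjusted over the list alone), the collagen gene Col1a2 at −3.50 ± 0.29 and Emcn at 1.47 ± 0.18, the latter not past the threshold with normexp. The median was −0.18, with −0.33 on slide 1 and −0.26 on slide 2 (camera adjusted p = 0.71). The list of sex-linked genes had 4 measured members, too few for a test (median 0.16; 0.39 and −0.15), and Xist differed by 0.44 ± 0.48 (adjusted p = 0.55).

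Genes of proliferation and growth were lower in Runx1-deleted GMP, by small amounts in many members. Of 33 cell cycle genes, 21 fell and none rose (28 and none adjusted over the list alone). The median was −0.57, with −0.39 on slide 1 and −0.70 on slide 2 (camera adjusted p = 2.8e-08, adjusted p = 0.588 with an estimated correlation). The mitotic kinase genes Plk1 and Bub1 fell by 0.85 (SE 0.21; −0.75 and −0.95) and 0.82 (SE 0.16). Of 31 ribosome biogenesis genes, 11 fell and none rose (19 and none adjusted over the list alone), for example Nop56 (−0.49 ± 0.09) and Nolc1 (−0.61 ± 0.13). The median was −0.36, with −0.46 on slide 1 and −0.23 on slide 2 (camera adjusted p = 2.15e-05, adjusted p = 0.647 with an estimated correlation). Of 24 unfolded protein response genes, 11 fell and 1 rose (14 and 1 adjusted over the list alone). The median was −0.40, with −0.39 on slide 1 and −0.53 on slide 2 (camera adjusted p = 0.00077, adjusted p = 0.588 with an estimated correlation). Asparagine synthetase (Asns) fell by 3.86 (SE 0.38; −4.62 and −3.11), and Derl3 and the chaperone gene Hyou1 by 1.63 (SE 0.17) and 0.82 (SE 0.17).

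Among cell cycle brakes and D cyclins, 6 of 18 were higher and 3 lower (7 and 4 adjusted over the list alone). The median was 0.38, with 0.22 on slide 1 and 0.38 on slide 2 (camera adjusted p = 0.154). Btg1 rose by 0.88 ± 0.11 and cyclin D1 (Ccnd1) fell by 0.81 (SE 0.18). One Cdkn2a probe, well above background on 1 of 4 wt arrays, was higher by 3.05 ± 0.47, but the other lay at −0.35 and the call ended with normexp. Glycolysis and hypoxia genes were higher in 2 of 21 cases and lower in 6 by either adjustment, with a median of −0.23 (−0.19 and −0.25), and did not pass as a list (adjusted p = 0.133). Of 22 cholesterol synthesis genes, none was higher and 4 were lower by either adjustment, with a median of −0.20 (−0.24 and −0.17, adjusted p = 0.123). Hexokinase 2 (Hk2, −0.78 ± 0.09) and Hmgcs1, an early enzyme of sterol synthesis (−0.73 ± 0.11), were among the lower members. The call of Sqle (−0.69 ± 0.21) ended with the replicate block (adjusted p = 0.0949) and without ko replicate 1 (0.109).

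Interferon response genes rose together. Of 33, 22 were higher and 1 lower (25 and 3 adjusted over the list alone), with a median of 0.81 (0.92 and 0.76; adjusted p = 1.1e-12, adjusted p = 0.492 with an estimated correlation). The antiviral genes Ifit1 and Rsad2 rose by 2.09 ± 0.19 (2.19 and 1.99) and 1.96 ± 0.16 (2.03 and 1.88), and Irf7, a transcription factor of the interferon response, by 1.80 ± 0.14 (1.63 and 1.96). Of 25 Toll-like receptor and NF-kB genes, 10 rose and 2 fell (12 and 2 adjusted over the list alone), with the feedback inhibitor Socs3 at 2.62 ± 0.42, Bcl3 at 1.70 ± 0.17 and the cytokine gene Il6 at −1.74 ± 0.28. The median was 0.38, with 0.31 on slide 1 and 0.41 on slide 2 (camera adjusted p = 0.00721, adjusted p = 0.588 with an estimated correlation). Of 19 p53 target genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone). The median was 0.22, with 0.37 on slide 1 and 0.39 on slide 2 (camera adjusted p = 0.0133, adjusted p = 0.492 with an estimated correlation), and the list did not pass on slide 1 alone (adjusted p = 0.114). The death receptor gene Fas rose by 1.60 ± 0.12 and Bbc3 by 1.11 ± 0.22.

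Immediate early and heat shock genes passed as a list although none of its 19 members did by either adjustment. The median was 0.92, with 0.66 on slide 1 and 1.22 on slide 2 (camera adjusted p = 0.00881, adjusted p = 0.647 with an estimated correlation). Its smallest p was that of Btg2 (1.46 ± 0.50, adjusted p = 0.059), and the list did not pass without wt replicate 4 (adjusted p = 0.0631) or on slide 1 alone (0.207). Of 25 cytokine receptor genes, 7 were higher and 3 lower by either adjustment, including the interleukin 1 receptor Il1r1 (−2.52 ± 0.18), Il1rl1 (1.77 ± 0.30) and Csf2rb2 (1.56 ± 0.15). The median was −0.00, with 0.11 on slide 1 and −0.06 on slide 2 (camera adjusted p = 0.392). Of 14 genes described as RUNX1 targets in other work, 3 were higher and 2 lower (4 and 4 adjusted over the list alone). The median was −0.22, with 0.04 on slide 1 and −0.45 on slide 2 (camera adjusted p = 0.564). Prkcq rose by 1.97 ± 0.23 and Nfe2 by 0.64 ± 0.11, while Cebpa, a factor of granulocyte development, fell by 0.92 (SE 0.16) and Mpo narrowly. Median, mean and test differed in sign in the lists of erythroid, hematopoietic transcription factor, Hox and Meis, cytokine receptor and RUNX1 target genes, none of which passed.

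With an estimated correlation between genes, none of the 27 lists tested passed in this comparison (smallest adjusted p = 0.492, 2 lists at an unadjusted p under 0.05). Other divisions of the 8 arrays into equal groups called a median of 9 lists and up to 16, against 13 here. On slide 2 alone 180 genes were higher and 199 lower, against 1876 and 2340 on slide 1 alone. With normexp they were 922 and 1053, and the calls of Ctsg, Mpo, H2-Aa, Nolc1 and Sqle ended as well. Further lists passed in a few other settings only. Erythroid genes did so as lower on slide 1 alone (adjusted p = 0.0221) and as higher on slide 2 alone (3.03e-06) and without ko replicate 2 (0.0389). Cell cycle brakes passed with normexp (0.0498) and without the filter on dim probes (0.025), and cytokine receptor and transcription factor genes with normexp (0.0495 and 0.0318). Cholesterol synthesis genes passed with only the wt and ko arrays (0.0361) and with quantile normalization (0.0498), and glycolysis genes without wt replicate 4 (0.0495).

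**Figure D2:**
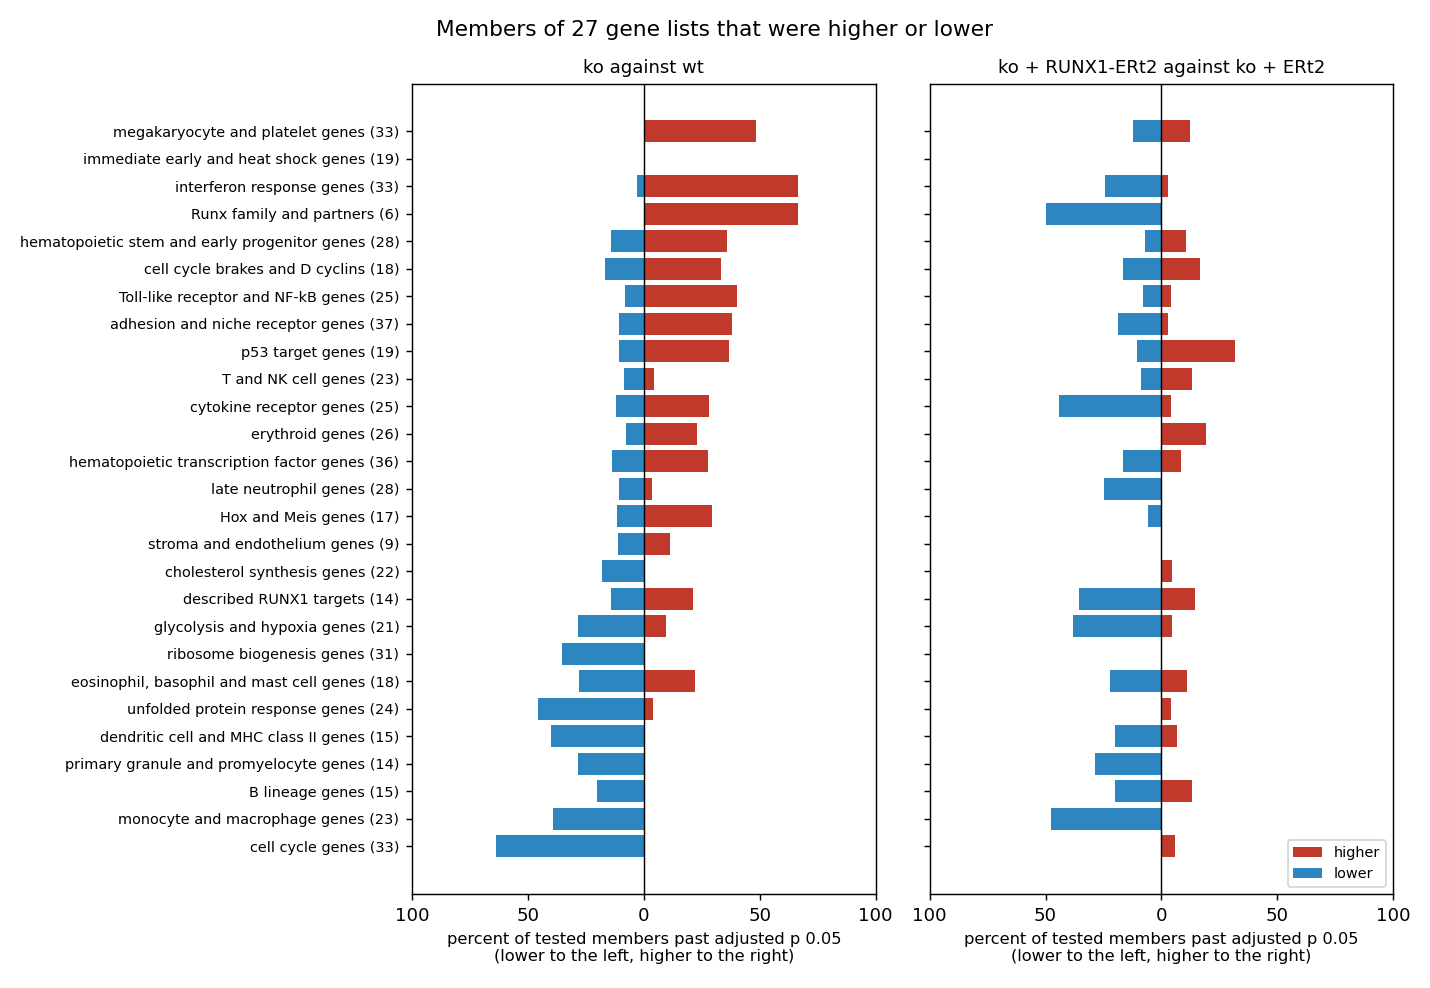
Percent of the tested members of each of 27 gene lists that passed an adjusted p of 0.05 over all genes, lower members to the left and higher members to the right, for ko against wt and for RUNX1-ERt2 against ERt2. In ko against wt, 22 of 33 interferon response genes were higher and 21 of 33 cell cycle genes lower.

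The second comparison asked what RUNX1-ERt2 changes in transplanted Runx1-deleted GMP, against ERt2 alone. Surrogate light chain genes of early B cells and the cytokine gene Il6 were among the largest rises: Vpreb2 was at least 34.4-fold and Il6 at least 25.1-fold higher with RUNX1-ERt2, and Vpreb1 rose by 5.86 ± 0.45 (limma adjusted p = 3.9e-05). Clic3 (at least 47.2-fold), the fatty acid transporter Slc27a2 (45.7-fold), the ATP-gated channel P2rx5 (30.5-fold), Timp3 (14.8-fold), Ptpn13 and Tmem151b (both 13.2-fold) were also far brighter with RUNX1-ERt2, as lower bounds, and Tac2 rose by 5.49 ± 1.02 (well above background on 1 of 2 ERt2 arrays). F13a1, a coagulation factor subunit of monocytes, fell by 5.40 (SE 0.50, adjusted p = 0.00012), the protease inhibitor Slpi by 4.82 (SE 0.38) and the neutrophil lectin Fcnb lay at −4.48 ± 0.88. In all, 1830 genes were higher and 1588 lower, 1016 and 824 of them by at least 2-fold. With the array median the counts were 1352 and 1468 and with the series matrix 1330 and 1502, so here too the balance depends on the scaling, and the lower count was 934 to 1058 without 1 of the transplanted arrays.

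Other large falls were those of Glt1d1 (−5.20 ± 0.72), Tctex1d1 (−5.47 ± 1.01), Mgam (−4.43 ± 0.74), Clec4b2 (at least 22.8-fold), Rgs8 (at least 12.9-fold) and Sh3tc2 (at least 4.63-fold). Glt1d1, Tctex1d1, Mgam and Ambp were well above background on 1 of 2 RUNX1-ERt2 arrays. The call of Clec4b2 ended without RUNX1-ERt2 replicate 2 (adjusted p = 0.0735), that of Ambp (−4.40 ± 0.93) without ERt2 replicate 1 (0.0551), and that of Sh3tc2 with normexp.

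Myeloid genes were lower with RUNX1-ERt2 than with ERt2. The monocyte, late neutrophil and primary granule lists were in turn higher in ERt2 than in ko (medians 1.13, 2.31 and 1.49). The falls are thus relative to ERt2, and RUNX1-ERt2 was not compared with ko. Of 23 monocyte and macrophage genes, 11 fell and none rose (13 and 1 adjusted over the list alone), including F13a1, the mannose receptor Mrc1 (−2.83 ± 0.36) and the receptor of the macrophage growth factor, Csf1r (−2.44 ± 0.42). The median was −1.27 (camera adjusted p = 3.8e-06, adjusted p = 0.725 with an estimated correlation). Without the slide term Mrc1 did not pass (adjusted p = 0.169). Of 28 late neutrophil genes, 7 fell and none rose (9 and none adjusted over the list alone). The median was −1.86 (camera adjusted p = 5.6e-05, adjusted p = 0.734 with an estimated correlation). The antibacterial protein gene Pglyrp1 fell by 3.14 (SE 0.51) and Mcemp1 by 2.29 (SE 0.30), and Abca13 was at least 7.75-fold lower. Primary granule and promyelocyte genes fell in 4 of 14 cases and rose in none (6 and none adjusted over the list alone): Fcnb, neutrophil elastase (Elane, −2.38 ± 0.52), lysozyme (Lyz2, −2.30 ± 0.51) and Ctsg (−1.41 ± 0.33). The median was −0.58 (camera adjusted p = 0.00272, adjusted p = 0.734 with an estimated correlation). Apart from Fcnb their calls ended without single arrays (highest adjusted p = 0.086 for Elane and 0.107 for Ctsg, both without RUNX1-ERt2 replicate 2, and 0.0839 for Lyz2, without ERt2 replicate 1).

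Erythroid genes were higher with RUNX1-ERt2, with 5 of 26 up and none down (6 and none adjusted over the list alone). The median was 1.68 (camera adjusted p = 0.00102, adjusted p = 0.787 with an estimated correlation). Tmod1, a protein of the red cell membrane skeleton, was at least 6.63-fold higher, a call that ended with normexp. The calls of the blood group antigen Kel (2.33 ± 0.57) and of Car2 (2.21 ± 0.57) ended without ERt2 replicate 2 (adjusted p = 0.121 and 0.153). Of 33 interferon response genes, 8 fell and 1 rose (8 and 2 adjusted over the list alone). The median was −0.34 (camera adjusted p = 0.0233, adjusted p = 0.787 with an estimated correlation). Usp18 (1.53 ± 0.30) was the riser, and Zbp1 (−0.81 ± 0.24) and Rsad2 (−0.75 ± 0.22) were among those that fell. Their calls ended without single arrays (highest adjusted p = 0.0554 without RUNX1-ERt2 replicate 2, 0.239 without ERt2 replicate 2 and 0.204 without ERt2 replicate 1, in this order), and those of Zbp1 and Rsad2 also with the replicate block (0.0794 and 0.0840). The list itself did not pass without ERt2 replicate 2 (0.156), without RUNX1-ERt2 replicate 2 (0.0635), without the slide term (0.0793) or with probes well above background on all 12 arrays (0.0519).

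Of 19 p53 target genes, 6 rose and 2 fell with RUNX1-ERt2 (8 and 2 adjusted over the list alone). The median was 0.37 (camera adjusted p = 0.0382, adjusted p = 0.725 with an estimated correlation, 0.0875 without ERt2 replicate 2, 0.0629 with the adjustment for probe GC and 0.0504 with the crossed pairing). Phlda3 rose by 2.97 ± 0.34, the cell cycle inhibitor Cdkn1a by 2.73 ± 0.37, Zmat3 by 2.58 ± 0.37 and Perp by 2.28 ± 0.33. Cytokine receptor genes fell in 11 of 25 cases and rose in 1 (12 and 4 adjusted over the list alone), with the interleukin 6 receptor chains Il6st (−1.80 ± 0.34, adjusted p = 0.11 without the slide term) and Il6ra (−1.50 ± 0.21) beside Csf1r. The median was −0.67 (camera adjusted p = 0.00651, adjusted p = 0.725 with an estimated correlation). Glycolysis and hypoxia genes fell in 8 of 21 cases and rose in 1 (11 and 2 adjusted over the list alone), with pyruvate kinase (Pkm) at −1.49 ± 0.23 and the glucose transporter Slc2a3 at 1.11 ± 0.20. The median was −0.43 (camera adjusted p = 0.00651, adjusted p = 0.725 with an estimated correlation).

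The other lists did not pass in this comparison with the main fit. Of 15 B lineage genes, 2 were higher and 3 lower by either adjustment (adjusted p = 0.897): beside Vpreb1, Igll1 was at least 24.4-fold higher, and Dntt, the enzyme that adds nucleotides at antigen receptor joints, fell by 2.98 (SE 0.44). Of 15 dendritic cell and MHC class II genes, 1 was higher and 3 lower by either adjustment (adjusted p = 0.363). Itgax was the higher one, at 4.40 ± 0.43, and Batf3 (−2.14) and Flt3 (−1.12) were among the lower. The calls of Batf3 and Flt3 ended with the replicate block (limma adjusted p = 0.0618 and 0.0709). Of 18 eosinophil, basophil and mast cell genes, 2 were higher and 4 lower (3 and 7 adjusted over the list alone; adjusted p = 0.163), Ms4a2, the beta chain of the IgE receptor, at 2.71 ± 0.28. The T and NK cell list (3 of 23 higher, 2 lower; 4 and 2 adjusted over the list alone; adjusted p = 0.22, but 0.00922 without RUNX1-ERt2 replicate 1 and 0.0395 without ERt2 replicate 1) held Nkg7 at −1.57 ± 0.27. The adhesion list (1 of 37 higher, 7 lower; 1 and 8 adjusted over the list alone; adjusted p = 0.0536, and 0.0487 with the replicate block) held Vcam1 at −3.72 ± 0.61 and Itga9 at −2.50 ± 0.28. Among cell cycle brakes (3 of 18 higher, 3 lower; 4 and 4 adjusted over the list alone; adjusted p = 0.922), Ccnd1 fell by 1.96 (SE 0.26).

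Stem and early progenitor genes (3 of 28 higher, 2 lower; adjusted p = 0.787) included Ctnnal1 at 1.75 ± 0.18. RUNX1 target genes of other work were higher in 2 of 14 cases and lower in 5 (4 and 5 adjusted over the list alone; adjusted p = 0.632). Megakaryocyte and platelet genes (4 of 33 higher, 4 lower; median 0.30; adjusted p = 0.501) passed as higher without RUNX1-ERt2 replicate 1 (median 0.93, adjusted p = 0.00361) and without ERt2 replicate 1 (0.65, 0.0468). Among the lower was Treml1 at −2.19 ± 0.56, whose call ended with the replicate block (limma adjusted p = 0.0547) and without RUNX1-ERt2 replicate 1. Gp1ba, among the higher, lay at 2.57, a call that also ended with the replicate block (0.054). Hematopoietic transcription factors (3 of 36 higher, 6 lower; adjusted p = 0.115) included Lyl1 at −1.43 ± 0.17 and Hhex at 1.10 ± 0.13. The counts of these lists other than that of the RUNX1 targets were the same adjusted over the list alone. Cell cycle (2 of 33 higher, none lower; adjusted p = 0.223), cholesterol synthesis (1 of 22 higher, none lower; adjusted p = 0.509) and unfolded protein response genes (1 of 24 higher, none lower; adjusted p = 0.064, and 0.047 with the replicate block) had the same counts by either adjustment, with Cdc6 at 1.34 ± 0.21, Lss at 1.19 ± 0.21 and Trib3 at 2.34 ± 0.36. The Cdk1 probe, of 18.3% GC, rose by 3.09 ± 0.22, but another probe of the gene lay at −0.25.

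No member passed by either adjustment in the stroma (9 members, adjusted p = 0.683; Lepr at 0.80 ± 0.29, adjusted p = 0.084, and 0.0293 with the replicate block), ribosome biogenesis (31 members, adjusted p = 0.708; Nop58 at 0.34 ± 0.14, adjusted p = 0.14) and immediate early lists (19 members, adjusted p = 0.163; Egr1 at 4.90 ± 1.59, adjusted p = 0.062, and 0.0494 with the replicate block, well above background on 1 of 2 ERt2 arrays). Of 25 Toll-like receptor and NF-kB genes, 1 was higher and 2 lower by either adjustment (adjusted p = 0.181), Ly96 at −1.37 ± 0.23. Of 17 Hox and Meis genes none was higher and 1 lower (none adjusted over the list alone; adjusted p = 0.103, and 0.047 with the replicate block). The sex-linked gene with the smallest p was Ddx3y (−1.21 ± 0.56, adjusted p = 0.18). Median, mean and test differed in sign for B lineage genes, cell cycle brakes and Toll-like receptor genes. Several of these lists passed in other settings: adhesion genes in 10 (adjusted p down to 0.0016), unfolded protein response genes in 8 (0.0103), Runx family genes in 7 (0.0329), and Hox and Meis (0.022), cell cycle (0.0271) and immediate early genes (0.0264) in 3 each. Transcription factor genes did so in 2 (0.0267), and ribosome biogenesis (0.0376), cholesterol synthesis (0.0368) and eosinophil, basophil and mast cell genes (0.0443) in 1 each. Each of these groups was measured on 1 slide of its own, so slide and group cannot be told apart. With an estimated correlation none of the 27 lists passed (smallest adjusted p = 0.725, 1 list at an unadjusted p under 0.05). With normexp 726 genes were higher and 665 lower, and the calls of Timp3, Abca13, Zbp1, Rsad2 and Lss ended too.

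The series asks for target genes of Runx1, and the 2 comparisons, which share no array, were set against each other. Scin fell by 5.70 on deletion and rose by 4.41 ± 0.59 with RUNX1-ERt2. Arhgef25 lay at −4.04 ± 0.50 and 3.72 ± 0.70, the aldehyde dehydrogenase gene Aldh1a7 at −3.58 ± 0.45 and 3.54 ± 0.64, and the muscle LIM protein gene Csrp3 at −2.85 ± 0.28 and 2.87 ± 0.39. The trefoil peptide gene Tff1 was at least 7.90-fold higher on deletion and at least 5.20-fold lower with RUNX1-ERt2. Npdc1 (−4.11 ± 0.37 on deletion), Matn2 (−4.31 ± 0.43) and Sfrp4 (−3.04 ± 0.40) rose with RUNX1-ERt2, Npdc1 by at least 3.46-fold, Matn2 by 3.15 ± 0.61 and Sfrp4 by at least 10.6-fold. These 3 were well above background on 1 of 4 ko arrays, and Scin, Aldh1a7 and Matn2 on 1 of 2 ERt2 arrays, so their sizes are less certain. Prss34 rose by 3.29 ± 0.79 and Epdr1, at −3.17 ± 0.56 on deletion, by 3.04 ± 0.79 with RUNX1-ERt2. These calls ended without ERt2 replicate 1 (adjusted p = 0.12) and without ERt2 replicate 2 (0.149), and that of Epdr1 also with the replicate block (0.0718). With normexp the rises of Npdc1 and Matn2 with RUNX1-ERt2 and both Tff1 calls ended. On the arrays of the transplanted groups alone 31 of 103 named genes lost their call, among them Scin (adjusted p = 0.0548), Arhgef25 (0.0889), Matn2 (0.0898), Prss34 (0.155) and Tff1 (0.0531).

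Of the genes that passed in both comparisons, 815 changed in opposite directions, 439 of them higher on deletion and lower with RUNX1-ERt2 and 376 the reverse. In the same direction changed 361, 143 higher and 218 lower in both. Independent lists of these sizes would share 435.8 genes of opposite and 430.2 of the same direction (Fisher's exact test of same against opposite sign, two-sided, odds ratio 0.189, p = 1.2e-41, across genes, which are not independent replicates). Over all 17907 genes the correlation of the log2 differences was weak (Pearson −0.147, Spearman −0.14), and 61.2% of the 4537 genes changed on deletion had the opposite sign with RUNX1-ERt2. The opposite and same-direction counts fell together, to 238 and 94 with normexp, 353 and 144 with only the arrays of each comparison in its fit, 516 and 199 without the slide term and 465 and 175 without the filter on dim probes. They were 541 and 225 without wt replicate 1 and 538 and 209 without wt replicate 2, but 491 and 316 without ERt2 replicate 1, where the excess of opposite genes was smaller. The correlation was −0.066 without ERt2 replicate 1, and correlations as far from 0 arose in 13 of the 35 divisions of the wt and ko arrays.

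The third comparison described ERt2 GMP against the Runx1-deleted GMP of mice that had not been transplanted, as background to the second. In it the replicate block and the crossed pairing contrast the replicate 1 levels of the groups and not their means. Blocked and crossed values therefore do not test the same difference as the main fit. For Fosb the blocked difference was −5.34. Immediate early genes were far lower in ERt2 GMP: Egr1 fell by 8.72 (SE 1.38, limma adjusted p = 0.00067; well above background on 1 of 2 ERt2 arrays), Fosb lay at −7.35 ± 1.39 (adjusted p = 0.0534 with the replicate block), and Zfp36 was at least 104-fold lower on a probe of 21.7% GC. Of the 19 genes of the immediate early and heat shock list, 15 fell and none rose by either adjustment. The median was −3.12 (camera adjusted p = 0.00121, adjusted p = 0.79 with an estimated correlation). The acute phase genes Orm2 (5.04 ± 0.52) and Orm1 (4.61 ± 0.77), each well above background on 1 of 4 ko arrays, rose, and Mreg (at least 23.7-fold), the retinoic acid receptor Rarb (6.29-fold) and Lrp1b (5.58-fold, not past the threshold with normexp) were higher as lower bounds. Ctdsp2 (−7.28 ± 0.12) and Slc25a22 (at least 48.2-fold lower) were measured by probes of 28.3% and 18.3% GC, and another Ctdsp2 probe lay at −0.69. Ctdsp2 was well above background on 1 of 2 ERt2 arrays.

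Granulocyte genes were higher in ERt2 than in ko GMP, but with an estimated correlation this list call and every other in this paragraph was lost (adjusted p = 0.79 with an estimated correlation for each). Of 28 late neutrophil genes, 20 rose and none fell by either adjustment (median 2.31; adjusted p = 0.00157), with the antimicrobial peptide gene Camp at 4.55 ± 0.94 and Chil3 at 4.54 ± 0.98. Of 14 primary granule genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone; median 1.49; adjusted p = 0.00842), with Fcnb at 4.18 ± 0.76 and Prss57 at 2.64 ± 0.48. Monocyte genes passed as well (13 of 23 higher, 3 lower, 16 and 3 adjusted over the list alone), at a median of 1.13 (adjusted p = 0.0165, 0.105 with the replicate block). Dendritic cell and MHC class II genes (9 of 15 higher, 1 lower) had a median of 1.03 (adjusted p = 0.0424), with 0.127 under the replicate block, 0.159 without ERt2 replicate 1 and 0.0534 without ko replicate 4. Glycolysis genes (15 of 21 higher, 1 lower) had a median of 0.68 (adjusted p = 0.0102) and unfolded protein response genes (13 of 24 higher, none lower) one of 0.75 (adjusted p = 0.0297, 0.0849 without ERt2 replicate 2). Mpeg1 rose by 2.33 ± 0.50, Cd74 by 3.40 ± 0.46, Pkm by 1.63 ± 0.20 and Chac1 by 3.48 ± 0.56. Megakaryocyte and platelet genes were lower as a list (2 of 33 higher, 17 lower, median −1.20, adjusted p = 0.00842). So were stem and early progenitor genes (3 of 28 higher, 15 lower, median −0.87, adjusted p = 0.0209), with 0.0539 under the replicate block and 0.0849 without ERt2 replicate 2. T and NK cell genes (1 of 23 higher, 11 lower, median −1.46, adjusted p = 0.0211) did not pass without ERt2 replicate 2 (0.113). Members of these lists were Treml1 at −2.65 ± 0.49, Slamf1 at −3.38 ± 0.44 and Gzma at −4.09 ± 1.10, the last not past the threshold without ERt2 replicate 2 (0.0579). In further settings the monocyte list lost its call 4 times (adjusted p = 0.0567 to 0.465), the dendritic cell list 7 times (0.0611 to 0.297) and the T and NK cell list 2 times (0.12 and 0.18). The unfolded protein response list lost it with the array median (0.0549), the series matrix (0.0542), only the arrays compared (0.0518), no filter on dim probes (0.147) and probes well above background on all 12 arrays (0.12). The megakaryocyte list lost it with the crossed pairing (0.127) and the glycolysis list without the filter on dim probes (0.0561). The lists named without a second count had the same counts adjusted over the list alone. Slamf1 was well above background on 1 of 2 ERt2 arrays and Chac1 on 3 of 4 ko arrays.

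The remaining 17 lists did not pass. Interferon response genes were lower in 17 of 33 cases and higher in 6 (18 and 6 adjusted over the list alone; median −0.42; adjusted p = 0.0611, but 0.0110 with the replicate block and under 0.05 in 12 further settings), Iigp1 at −3.06 ± 0.21. Counts over all genes, with the adjusted p of the list, were 3 lower of 6 Runx family genes (adjusted p = 0.374; Runx3 at −0.95 ± 0.13 with another probe at 0.89), 3 higher and 2 lower of 26 erythroid genes (0.679; Alas2 at 2.57 ± 0.49), and 10 and 13 of 37 adhesion genes (0.679; Notch1 at −3.86 ± 0.55). They were 2 and 6 of 15 B lineage genes (0.211, and 0.0133 without the filter on dim probes; Dntt among the lower), 2 and 2 of 9 stroma genes (0.527; Lepr at −3.38 ± 0.25), 14 and 6 of 33 cell cycle genes (0.374; Cdk1 at −4.86 ± 0.19 on the probe of 18.3% GC, with another at 0.58). They were 11 and 5 of 31 ribosome biogenesis genes (0.302; Nop16 at 1.23 ± 0.19) and 4 and 11 of 25 Toll-like receptor genes (0.564; Ccl3 at −5.21 ± 1.09, adjusted p = 0.0842 with the replicate block, well above background on 1 of 2 ERt2 arrays), and these counts were the same adjusted over the list alone. They were 10 and 10 of 36 transcription factor genes (0.99; Klf5 at 2.48 ± 0.37), 4 and 5 of 17 Hox and Meis genes (0.664; Meis1 at −1.32 ± 0.25) and 10 and 5 of 25 cytokine receptor genes (0.565). They were 6 and 4 of 22 cholesterol synthesis genes (0.679; Mvd at 1.70 ± 0.15) and 7 and 3 of 14 RUNX1 target genes (0.679; Elane at 2.21 ± 0.45), again by either adjustment. Over all genes and adjusted over the list alone they were 6 and 1 against 5 and 1 of 18 eosinophil, basophil and mast cell genes (0.312; Prss34 at 4.26 ± 0.68, well above background on 2 of 4 ko arrays), 1 and 6 against 1 and 4 of 18 cell cycle brakes (0.564; Btg2 at −3.12 ± 0.61, adjusted p = 0.0738 with the replicate block) and 3 and 5 against 3 and 4 of 19 p53 target genes (0.564). Median, mean and test differed in sign for cell cycle and transcription factor genes, and the sex-linked gene Uty lay at 0.61 ± 0.43 (adjusted p = 0.25) with another probe at −2.80.

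In all, 10189 genes differed, 5408 higher and 4781 lower, 1627 and 2743 of them by at least 2-fold. With the array median 6709 were higher and 3746 lower, with the series matrix 6535 and 3786, and with normexp 3674 and 2740. The balance and the total thus depend on the scaling. The difference followed the GC content of the probe, from a median of −2.92 for the 101 genes with probes of up to 26% GC and −1.14 for the 130 genes between 26% and 30% to 0.52 for the 1705 genes above 54%, and transplantation, retroviral infection, tamoxifen and slide cannot be told apart here. The second comparison had a weaker trend the other way, with medians of 0.45, 0.51 and −0.10 in these bins, so its rises on low-GC probes are less certain.

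**Figure D3:**
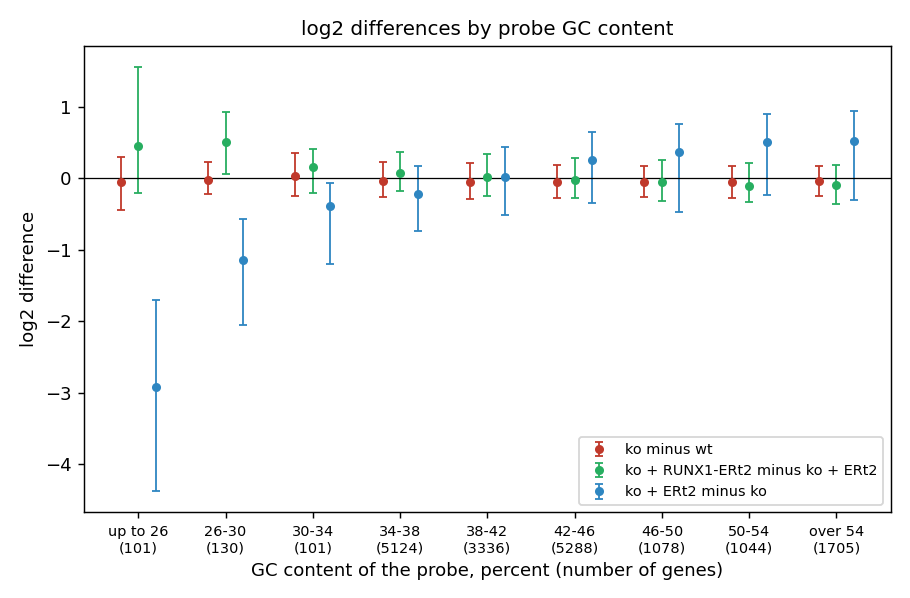
Median and quartiles of the log2 difference in bins of probe GC content, with the number of genes in each bin, for the 3 comparisons. The median for ERt2 against ko was −2.92 in the lowest bin and 0.52 in the highest, whereas that for ko against wt stayed between −0.06 and 0.03. That for RUNX1-ERt2 against ERt2 was 0.45 in the lowest bin, 0.51 in the next and −0.10 in the highest.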

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

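No test of this part was chosen after its result was seen: the criterion, a large gap of 1 array to the others relative to the range, was set in advance. The set of genes scanned was reduced afterwards, without regard to their values. In 11 of 242 sets of 4 arrays (4.55%; 117 named genes and 4 array measures in wt and in ko), 1 array lay far from the other 3, and chance marks about 1 in 20 sets. Values are log2 signal relative to the 75th percentile of the array. The main-fit comparisons of these genes between ko and wt stand in the report, other than those of Fcrla and Tmod1. The Fcrla call in ko against wt ended without ko replicate 4 (limma adjusted p = 0.122, the highest of 7 such values).

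In wt replicate 4, which holds 3 of the 11, Irf8 lay at 3.876 against 4.68 to 4.73 on the other wt arrays, Meis1 at 3.338 against 2.83 to 2.90 and Plk1 at 3.146 against 3.69 to 3.74. In wt replicate 3, Rsad2 lay at −2.82 against −2.04 to −1.93 and Lck at 0.1904 against 0.50 to 0.53, and in wt replicate 1 Tmod1 lay at −8.048 against −7.37 to −7.24. In ko replicate 4, Plk1 lay at 1.982 against 2.92 to 3.02 and Fcrla at −5.402 against −4.53 to −4.46. In ko replicate 3, Asns lay at −0.387 against −1.76 to −1.60 and Jam3 at 1.555 against 1.77 to 1.80, and in ko replicate 1 Nrg3 lay at −2.632 against −3.35 to −3.31. No explanation was tested for these single values.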

How the results depend on the processing

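The GC and crossed-pairing tests, and the count of list calls with the estimated correlation, were chosen only after the results were seen. The list test with an estimated correlation was itself planned beside the preset one. Of 121, 103 and 63 named genes in the 3 comparisons, 42, 43 and 36 kept direction and side of the threshold in every setting in which they were tested. So did 5, 7 and 15 of 27 lists. With probes well above background on all 12 arrays, only 90, 69 and 41 of the named genes were tested. With normexp, 922 genes were higher and 1053 lower in ko, 726 higher and 665 lower with RUNX1-ERt2, 238 were opposite and 6414 differed between ERt2 and ko; Tmod1 in ko against wt turned to −0.229 (adjusted p = 0.781). Lower genes in ko were 1397 with the array median (57.3% of calls higher, against 45.5%) and 1328 with the series matrix (58.7%). In ERt2 against ko 64.2% and 63.3% of calls were then higher, against 53.1%, and 68.3% without the dim filter. That setting, which tested 30119 genes, gave 465 opposite genes, a correlation of −0.0902 and 15476 genes between ERt2 and ko; 516 were opposite without the slide term. With only the arrays compared, fewer samples, 885 were higher, 769 lower and 353 opposite. At 2-fold or more, 655 and 627 genes passed in ko, 1016 and 824 with RUNX1-ERt2, 245 opposite and 4370 in the third comparison. Uty in ERt2 against ko turned to −1.095 (adjusted p = 0.00998) as a mean of probes, and the erythroid list in ko to −1.248 on slide 1 alone (adjusted p = 0.0221), with 0.89 on slide 2. Slide 2 alone gave 180 higher and 199 lower, against 1876 and 2340 on slide 1 alone, which held as many wt and ko arrays. With an estimated correlation 0 of 31 list calls passed. What caused these changes was not tested.

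Without 1 array, higher genes in ko ranged from 1387 to 2250 and lower ones from 1444 to 2585; the lower count fell over 1.5 times without wt replicate 1 (1514), wt replicate 2 (1453), ko replicate 1 (1493), ko replicate 2 (1629) and ko replicate 4 (1444). Higher genes with RUNX1-ERt2 ranged from 1244 to 1937 and lower ones from 934 to 1745 (971 and 1058 without ERt2 replicates 1 and 2, 1047 and 934 without RUNX1-ERt2 replicates 1 and 2). Opposite genes ranged from 491 to 886 (541, 538 and 491 without wt replicate 1, wt replicate 2 and ERt2 replicate 1), the correlation from −0.2167 to −0.066 (the latter without ERt2 replicate 1), genes in the third comparison from 7459 to 10521 and list calls from 30 to 36. With the replicate block 1781 genes were higher and 1920 lower in ko, 1684 and 1408 with RUNX1-ERt2, 634 opposite and 7383 in the third comparison, with the correlation at −0.1466 and 33 list calls; among the named genes of ko against wt it also ended the calls of Perp, Pou2af1 and Rrp12 (adjusted p = 0.0714, 0.0563 and 0.0657). The crossed pairing gave 2160 and 1924 with RUNX1-ERt2 and 8182 in the third comparison. The blocked and crossed counts of the third comparison contrast replicate 1 levels, not group means. The median difference of all genes lay at −0.15 in ko and 0.156 in ERt2 with normexp, at 0.25 and 0.24 in ERt2 with the array median and the matrix, and at −0.148, −0.146 and 0.38 in the 3 comparisons without the dim filter. After the GC adjustment 2203 and 2163 genes passed in ko, 2001 and 1377 with RUNX1-ERt2 and 778 opposite. Signal over background limits what is called: 53.5% to 63.2% of probes were well above it.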

Other observations

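The gene families and all tests of this part were chosen only after the results were seen. In ko against wt, most members of 3 further groups of neighbouring or related genes were higher, and no test of the groups as sets was made. All 4 measured CD200 receptor genes on chromosome 16 were higher, Cd200r1 by 1.71, Cd200r3 by 4.16 and Cd200r4 by 4.86, with Cd200r2 at least 1.84-fold higher, the last at −0.06 with normexp (adjusted p = 0.93); they have related sequences, so probes were not shown to be specific. In the imprinted region of chromosome 12, Dlk1 rose by 5.50, the non-coding RNA Meg3 by 4.21 ± 0.65 (5.73 on slide 1 and 2.68 on slide 2; well above background on 3 of 4 wt arrays) and Begain by 1.06 (0.35 with normexp, adjusted p = 0.469), Mirg was at least 2.76-fold higher (0.18 with normexp, adjusted p = 0.769), and Wdr25 lay at 0.00 (adjusted p = 0.996). Of 8 Gimap genes, GTPases of lymphocytes on chromosome 6, 6 were higher, led by Gimap8 (2.22 ± 0.40) and Gimap4 (1.99 ± 0.51); Gimap3 and Gimap7 did not pass, and Gimap7 turned to −0.36 with normexp.

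Some further antiviral and complement genes changed in 1 or both comparisons, again without a set test. Of 8 Oas genes 7 were higher in ko, Oas2 by 2.66 and Oas3 by 2.36, and with RUNX1-ERt2 these lay at −2.34 and −2.86, with 4 of the family lower and 2 higher. Serpina3f, Serpina3g and Serpina3i were higher in ko (1.83, 1.86 and 1.78, the last at 0.79 with normexp, adjusted p = 0.123), and the first 2 fell with RUNX1-ERt2 (−1.32 and −1.46), Serpina3i lying at −1.13 (adjusted p = 0.0518) and Serpina3h rising (0.74). Of 10 complement genes, 7 were lower with RUNX1-ERt2, among them C3 (−2.58), C1qc (−2.09), C4b (−1.99) and C1qa (−1.86), while in ko C4b (4.39) and C2 (3.21) were higher and C1ra (−1.25) and Cfp (−1.10) lower. Only C4b, C1ra and Cfp passed in both. Of 28 called family members in ko, 27 kept their direction with normexp and 24 their call; of 16 with RUNX1-ERt2, all 16 kept direction and 5 their call.

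Prss34 had the largest fitted fall of all named genes in ko, Fcer1a was not above background there and at least 54.4-fold lower, and the smallest within-slide change of Prss34, Fcer1a, Mcpt8 and Cd200r3 was 3.145 in size. These 4 were picked for their large changes, so this does not exclude slide as a cause. Fewer basophil-lineage cells as the only change would lower all 8 basophil genes measured, but 3 were higher, Cd200r3 (4.16), Cpa3 (1.92) and Il1rl1 (1.77), against Prss34, Fcer1a, Mcpt8 (−3.34) and Ms4a2 (−0.84) lower and Hdc (0.19) not past the threshold. The gene set was fixed with these values already seen, and the 3 risers are also expressed in other cells, so a mixture of fewer such cells with a rise in another type stays open. An effect of Runx1 on these genes within GMP may also contribute and was not tested apart from cell composition.

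Megakaryocyte and platelet genes rose in ko by a median of 1.19, and the smaller within-slide median was 1.297, so slide as the cause is argued against. RNA of platelets or megakaryocytes in the sorted cells could raise the list, and 6 abundant platelet genes had a median of 0.85 (SD 0.81), with Gp9 at 1.73, Ppbp at 1.60, Tubb1 at 1.14, Vwf at 0.56, Gp1bb at 0.08 and Pf4 at −0.24 (Ppbp well above background on 2 of 4 wt arrays and Tubb1 on 1). These genes and the bound were fixed with the values seen, and the median lies within 1 SD of the list's, so this source cannot be told apart from a change within GMP. The GMP gate would remove platelets and megakaryocytes only as far as the sort was pure.

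Probes of low GC content were far dimmer in ERt2 than in ko GMP. For 9 genes whose probe of at most 30% GC was lower by over 3, at a median of −4.59, other probes of at least 34% GC had a median of 0.22, and 0 of 9 lay below −1 against 20 of 32 genes with higher-GC probes (Fisher's exact test, two-sided, p = 0.00132), which is consistent with an effect of base composition on these probes. That test replaced a minimum of 20 genes, under which the result would have stayed undecided, and the replacement was made after the result was seen. After each array's average trend with GC content was taken off, 8979 genes still differed, so this trend was not the whole cause. Effects of base composition that depart from the average trend are not taken off, so the count cannot exclude them. Slide and labelling run cannot be told apart from transplantation and tamoxifen, as 0 slides held arrays of both groups. The biological difference between these groups was not tested separately.

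Of the 35 divisions of the 8 wt and ko arrays into groups of 4, 1, the real one, gave as many as 4537 genes, and the highest other gave 1568. That other division follows the slide and was fitted without the slide term. The 17 other divisions balanced over the slides and the other 7 that part all 4 replicate numbers gave 0, but these sets of 18 and 8 divisions are too few for a share under 0.05. As the real groups were balanced over the slides, only balanced divisions are comparable with them. The divisions therefore cannot exclude chance for the count of 4537, although no other came near it. For the 815 genes opposite in the other comparison, 1 of 35 gave as many, with 167 as the highest other. As 33 of the other 34 called no gene and so could hold no opposite one, this count adds nothing to the first, and chance stays open for it. For the correlation of −0.147, 13 of 35 lay as far from 0, up to 0.3152, and for the 13 lists called, 6 of 35 gave as many, up to 16, so chance is not excluded for either. Of single lists, the median of the Runx family list (0.507 against at most 0.444), the interferon list (0.812 against 0.768), the megakaryocyte list (1.19 against 1.16), the cell cycle list (0.574 against 0.538), the ribosome list (0.364 against 0.350) and the adhesion list (0.337 against 0.305) was larger in size than in any other division, whereas their camera p was as small in 2, 2, 4, 9, 9 and 1 of the 35. The remaining called lists were the stem, monocyte, dendritic cell, Toll-like receptor, immediate early, p53 and unfolded protein response lists. For these, in this order, a median as large arose in 4, 4, 5, 2, 9, 6 and 3 of the 35. Their camera p was as small in 5, 19, 10, 11, 21, 4 and 5, the real division included.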
